A study of Homo sapiens with 6 samples.

How the data were processed

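The series measured gene expression in MCF10A cells, a non-tumorigenic line of human mammary epithelial cells, with or without C/EBPbeta-2, an isoform of the transcription factor encoded by CEBPB. It holds 6 arrays: 3 labelled as cells with C/EBPbeta-2 and 3 labelled as MCF10A cells alone, called control here. The labels name the samples of each group biological replicates without saying what separated them, so the p-values measure the spread between these samples. Per the labels' protocols, total RNA was extracted on columns with DNase treatment, reverse transcribed from an oligo-dT primer carrying a T7 promoter, and transcribed into biotin-labelled RNA for Affymetrix arrays. How C/EBPbeta-2 was brought into the cells is not given in the sources used here.

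The deposited values are intensities, 1 per probe set and array, and the submitters' processing notes name RMA (robust multi-array average) with no version, background setting or software. RMA usually reports log2 values. The deposited intensities were on a linear scale, with a lowest value of 4.17, a highest value of 17825 and array medians of 22.0 to 23.6, and how they were brought to that scale is not given in the sources used here. They held 0 missing values and 0 values below 0. They were transformed to log2 with no pseudocount and no further normalization. No detection calls were used here, so low values have no stated background.

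Of 54675 probe sets, the 62 control probe sets of the manufacturer (names starting with AFFX) were set aside and 54613 were tested. The probe annotation gave 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Of the 41091, 41037 matched the gene reference by gene ID and 54 did not, and 0 symbols needed updating. Probe sets with several symbols were not named. A gene was read at its probe set with the highest mean over all 6 arrays, which gave 19775 genes.

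The comparison was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as C/EBPbeta-2 minus control over all 6 arrays with no covariate, two-sided, and with Benjamini-Hochberg adjustment over the probe sets or over the genes. A probe set or gene was called at an adjusted p under 0.05. All adjusted p-values come from limma. Standard errors are those of the fitted log2 difference, and SD is over the 3 arrays of a group. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, again with a correlation estimated from the data, and with fry. Camera compares the genes of a list with all other genes. Checks of single measures per array used exact two-sided permutation tests. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the values, and matplotlib 3.10.9 drew the plots.

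The design of these tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names CEBPB and IL1B, the 10 called genes with the largest rise and the 10 with the largest fall whose groups do not overlap, and up to 3 members of each list with the largest size of difference, called or not. IL1B was named because the study is known for it, and the lists were chosen to fit the study's epithelial, inflammatory and growth questions. The IL1B rise is therefore not a blind result, and the interleukin-1 list may not be one. Genes named outside this rule, such as CDH1, KRT13, SMAD7 and those called only within their list, were chosen after their values were seen. The lists were C/EBP family, interleukin-1 family and receptors, cytokines and chemokines, NF-kappaB response, acute-phase and complement, interferon-stimulated, EGF family ligands and receptors, epithelial junction and polarity, epithelial transcription and splicing factors, mesenchymal transition markers, fibroblast and other stromal cell markers, leukocyte markers, basal keratins and hemidesmosome, luminal and milk protein markers, cornified envelope and squamous differentiation, S100 and antimicrobial proteins, kallikreins and serine protease inhibitors, matrix proteases and inhibitors, collagens and matrix proteins, TGF-beta and BMP signalling, proliferation, G1 control and senescence, p53 targets, unfolded protein and amino acid stress, cholesterol biosynthesis, glycolysis and hypoxia response, oxidative stress and NRF2 response, and autophagy and lysosome. List members for which the annotation used here gave no probe set of their own were not analysed here.

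The alternatives left out each array in turn, added the replicate number as a block, applied quantile normalization again, centred each array on its median, left out dim probe sets (mean log2 under 4.52, which kept 27307 probe sets), used a trended and robust prior variance, array weights, the mean of a gene's probe sets, or no probe sets ending in _x_at or _s_at, and changed the threshold, the pooling of variances and the test of size. Chosen after seeing the data were a term for the level of the poly-A spike-in RNA, the ACTB 3' minus 5' value as a covariate, and a fit of the 4 arrays with a high spike level. The spike level is the mean log2 of 24 control probe sets, and arrays under 6 were called low.

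The steps were tested on simulated data for this comparison, over all 54613 probe sets, with 50 probe sets changed at each of 4 sizes. Limma recovered 5 of 50 at a log2 difference of 1, 30 of 50 at 2, 40 of 50 at 3 and 50 of 50 at 5, and 11 of 136 calls were false. The noise of this step was drawn independently for each probe set, without the variation that probe sets share on an array. Recovery and false calls on the real arrays may therefore differ. A shifted list was called and 0 of 100 unchanged lists were called. Where the genes of a list shared an effect of the array and no effect of the group, camera called 62 of 100 lists at the preset correlation and 0 of 100 with an estimated correlation. The size of that shared effect was chosen for the simulation, and recovery of a shifted list with an estimated correlation was not simulated. The number of arrays limits the precision: a permutation test of 3 against 3 cannot go below p = 0.1.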

Results

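Expression was compared between 3 arrays of MCF10A mammary epithelial cells with C/EBPbeta-2 and 3 arrays of control MCF10A cells, to find which genes differ with this isoform. The arrays correlated about as closely between groups as within them: Pearson's r over the log2 intensities of all probe sets was 0.949 to 0.980 within groups and 0.942 to 0.979 between groups. The largest source of variation did not follow the groups. Principal component 1 held 44.1% of the variance and placed C/EBPbeta-2 replicate 1 (-64.1) and control replicate 2 (-93.9) apart from the other 4 arrays, with an exact permutation p of 0.9 between groups (n = 3 per group). Component 2, with 22.2% of the variance, separated the groups at p = 0.1, the smallest that an exact test of 3 against 3 can give.

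The control probe sets also varied across the groups. Those of 18S ribosomal RNA averaged 12.19 (log2) on C/EBPbeta-2 replicate 1 and 12.17 on control replicate 2, at the low end of component 1. They averaged 5.62 on C/EBPbeta-2 replicate 2 and 8.05 on control replicate 1, at its high end. C/EBPbeta-2 replicate 3 (10.09) and control replicate 3 (10.33) lay between. The poly-A spike-in RNA averaged 3.85 (log2) on C/EBPbeta-2 replicate 2 and 3.98 on control replicate 1, against 7.21 to 8.25 on the other 4 arrays. These same 2 arrays had the largest excess of the ACTB 3' over the 5' control probe set, 1.32 and 1.48 against -0.04 to 0.64, a measure that rises with shortened RNA or cDNA. The same measure for GAPDH was not raised on them. It was 0.22 on C/EBPbeta-2 replicate 2 and 0.12 on control replicate 1, against 0.21 to 0.32 on the other 4 arrays. Between groups the ACTB value differed by 0.085 (exact permutation p = 0.8) and the GAPDH value by 0.0502 (exact permutation p = 0.4), each with n = 3 per group.

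**Figure D1:**
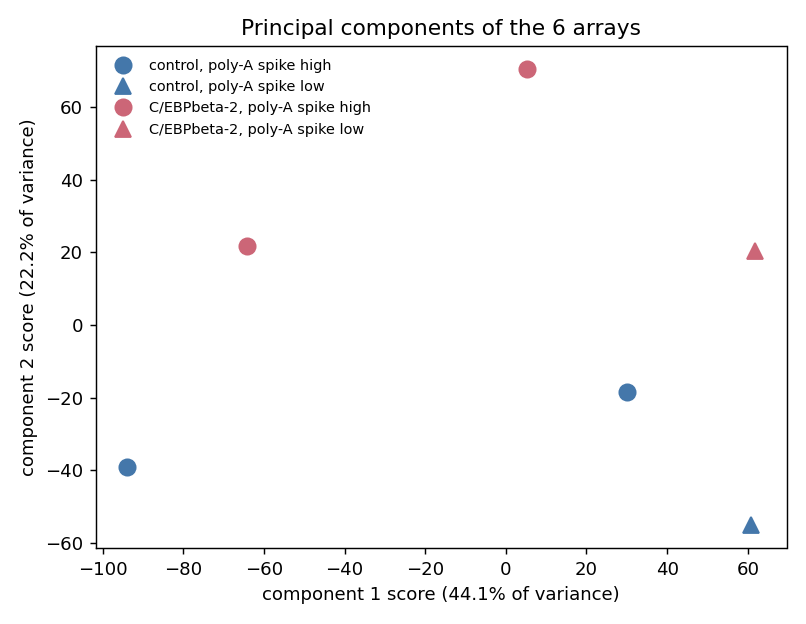
Scores of the 6 arrays on principal components 1 (44.1% of variance) and 2 (22.2%) of the log2 intensities, in log2 units, 1 point per array, with colour for the group and marker shape for the poly-A spike level. C/EBPbeta-2 replicate 1 (-64.1) and control replicate 2 (-93.9) lie at the low end of component 1.

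CEBPB, the gene that encodes C/EBPbeta-2, was not higher on the arrays labelled C/EBPbeta-2. Its probe set 212501_at read 10.29, 10.50 and 11.38 (log2 intensity) on these arrays and 11.27, 11.38 and 11.37 on the control arrays, a log2 difference of -0.62 (SE 0.29, adjusted p = 1.00). It was not called under any of 17 alternatives (adjusted p 0.366 to 1.00), and its difference was -0.77 at the low spike level and -0.54 at the high one. The position of the probes on the transcript was not used here, and probes outside an introduced sequence would not read it, so the labels could not be checked by this gene. Of the 7 measured members of the C/EBP family limma called 0, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05. CEBPA differed by -0.33 and CEBPD by 0.31, and the list was not called by camera (adjusted p = 0.593).

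With C/EBPbeta-2, 52 of 19775 genes changed, 19 rising and 33 falling, and every one of them changed at least 2-fold. By measured fold the largest rises were in IL1R2, the decoy receptor of interleukin-1 (338-fold), IL24, a cytokine of the interleukin-10 family (129-fold), TENM2, a teneurin adhesion receptor (75.1-fold), and IL1B, the secreted inflammatory cytokine interleukin-1 beta (32.1-fold). The largest falls were in SLPI, a secreted leukocyte protease inhibitor (77.6-fold), IRX3, an Iroquois homeobox factor (28.3-fold), PI3, the elastase inhibitor elafin (25.2-fold), and SPRR1B, a precursor of the cornified envelope (24.4-fold). IL1R2 (205403_at) rose from 4.54 ± 0.43 to 12.94 ± 0.86 and IL1B (39402_at) from 5.90 ± 0.15 to 10.91 ± 0.20, while SLPI (203021_at) fell from 11.89 ± 0.42 to 5.61 ± 0.36 (log2 intensity, mean ± SD, n = 3). The control means of IL24 (3.77) and TENM2 (3.47) and the C/EBPbeta-2 mean of PI3 (4.36) lay below every array median, and the control mean of IL1R2 (4.54) lay among the array medians. No detection calls were used here, so the size and order of these folds are uncertain. The log2 differences of IL1R2, IL1B and SLPI were 8.40 (SE 0.45, adjusted p = 0.00318), 5.01 (SE 0.17, adjusted p = 0.000695) and -6.28 (SE 0.28, adjusted p = 0.00195).

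Counted by probe set, 36 of 54613 were called, 15 up and 21 down, each at least 2-fold. At an unadjusted p under 0.05 there were 2175 probe sets and 1068 genes. The 2 groups did not overlap in 4159 probe sets (7.62%) and 1706 genes (8.63%), where chance gives 10%. The counts changed when 1 array was left out, which also leaves fewer arrays in the fit, and the 2 effects were not separated. The number of genes was 15 without C/EBPbeta-2 replicate 1, 18 without replicate 2 and 10 without replicate 3. It was 9 without control replicate 1 and 7 without control replicate 3, and 57 without control replicate 2, 28 of them shared with the 52. The number of probe sets in the same order was 12, 23, 5, 15 and 7, and 37 without control replicate 2. The groups did not overlap for any of the 52, so no left-out array could turn a sign, and their smallest size of difference was 1.28 at the low spike level and 1.19 at the high one. Leaving out 1 array moved the difference by over 1.5 times for 0 of the 26 named genes that were called and for 34 of the 65 that were not. This contrast largely follows from the call, which picks differences that are large against their spread on these same arrays, so it is no separate support. Of the 19 genes that rose, 5 had a control mean under 4.5, near the array medians, and of the 33 that fell, 8 had a C/EBPbeta-2 mean under it, where a fold is less certain.

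Among the other genes with the largest rises were SERPINB7 (log2 difference 4.48), SERPINB3 (4.47), STEAP1 (3.69), GLT8D2, a glycosyltransferase (3.14), and DOK7, an adaptor of the receptor kinase MuSK (2.86). Among those with the largest falls were KLK10 (-4.42), the complement component C3 (-3.67), SPRR1A (-3.42), TMTC1 (-3.29), the serine protease FAP (-3.21) and the adhesion receptor ADGRG2 (-3.20). IL1B, IL1R2, SLPI, IRX3, SPRR1B, KLK10 and C3 were called whichever array was left out. STEAP1 lost its call with a spike term (adjusted p = 0.0501) and after quantile normalization (0.0603), and TMTC1 with a spike term (0.0608) and with each array centred on its median (0.0590), where the alternatives ranged from 0.00692 to 0.248 and from 0.00906 to 0.259. STEAP1 lost it also without any array but control replicate 2 (adjusted p 0.102 to 0.212), DOK7 likewise (0.0503 to 0.121), TMTC1 likewise (0.110 to 0.259), and ADGRG2 likewise (0.0775 to 0.178). GLT8D2 lost it without C/EBPbeta-2 replicate 3 (0.0930), control replicate 1 (0.0775) or control replicate 3 (0.1002), and TENM2 without C/EBPbeta-2 replicate 1 (0.102) or any of control replicates 1 to 3 (0.0580 to 0.1502). KLK10 was read at a probe set with shared probes (209792_s_at). Its other probe set gave -0.87 (adjusted p = 0.965 without _x_at and _s_at probe sets, against 0.00111 to 0.139 under the other alternatives).

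**Figure D2:**
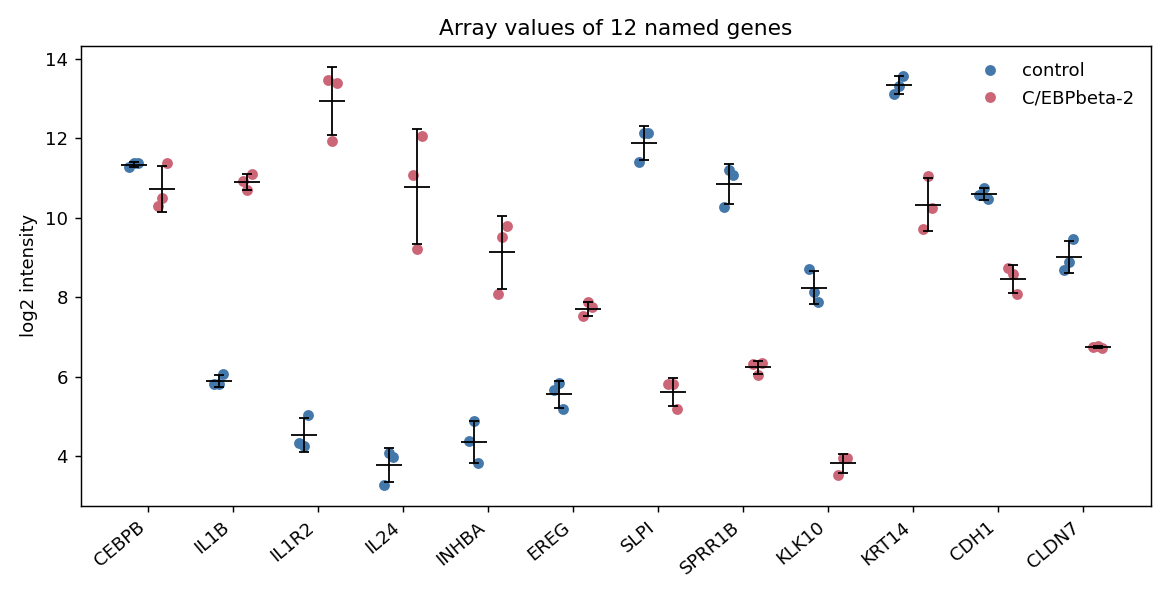
Log2 intensity of 12 genes on each array (points) with the mean and SD (bars) of the 3 C/EBPbeta-2 and 3 control arrays. IL1R2 averaged 12.94 against 4.54 and SLPI 5.61 against 11.89, while the CEBPB values of the groups overlapped.

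In the interleukin-1 family IL1B and IL1R2 rose, 2 of the 20 measured members, and 18 were not called. When adjusted over the list alone, 5 rose and 2 fell. The 5 were IL1B, IL1R2, the cytokine IL1A (0.71), and the receptor subunits IL18R1 (2.64) and IL1RL1 (3.53, SE 0.80, adjusted p = 0.281 over all genes). The 2 that fell were IL18 (-2.20) and the receptor antagonist IL1RN (-2.76). IL1RL1 was called in 2 of 17 alternatives (adjusted p 0.0117, without C/EBPbeta-2 replicate 2, to 0.785). The list was higher as a set at the preset correlation (mean log2 difference 0.78, median 0.08, camera adjusted p = 0.0178), and not called with an estimated one (adjusted p = 0.370). Its call was lost without C/EBPbeta-2 replicate 1 (adjusted p = 0.183), without control replicate 1 (0.0773), with a spike term (0.0609) and with the ACTB covariate (0.0851), and its mean was 0.49 at the low spike level and 0.92 at the high one.

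The other inflammatory lists were not called. Among cytokines and chemokines, 1 of 28 rose and 0 fell, also when adjusted over the list alone: IL24 (206569_at; log2 difference 7.01, SE 0.69, adjusted p = 0.0273), whose call was lost without any array but C/EBPbeta-2 replicate 2 (adjusted p 0.0617 to 0.175). The granulocyte factor CSF3 differed by 2.20 (adjusted p = 0.923; 1.32 without C/EBPbeta-2 replicate 3) and the chemokine CCL20 by -1.99 (adjusted p = 0.623). The mean of this list was 0.16, its median -0.06 and its camera direction down (adjusted p = 0.593). Limma called 0 of 15 NF-kappaB response genes, also when adjusted over the list alone, with 5 at an unadjusted p under 0.05 (list adjusted p = 0.304), with IER3 at 1.34 and SOD2 at -1.29 (0.89 and -0.56 without control replicate 1) and PTGS2 at 1.16. In the acute-phase and complement list (adjusted p = 0.304), C3 fell, 1 of 18 and 1 when adjusted over the list alone, from 10.89 ± 0.26 to 7.22 ± 0.26 (n = 3; adjusted p = 0.00325), and PTX3 (-1.80, but -1.05 without control replicate 1) and SERPINA3 (-1.44, but -0.47 without control replicate 2) were not called. Of 25 interferon-stimulated genes limma called 0, with 2 at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone, OAS1 (-1.37). IFI44L (-1.81) and IFI44 (-0.99) were not called and differed by -0.84 and -0.50 without control replicate 1, and the list had a mean of -0.02, a median of 0.07 and camera direction up (adjusted p = 0.936).

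Of 26 measured genes of the cornified envelope and squamous differentiation, 4 fell and 0 rose, and adjusted over the list alone 5 fell and 0 rose. The list fell as a set (mean -1.04, median -0.39, camera adjusted p = 6.57e-13), with adjusted p = 0.0289 with an estimated correlation. SPRR1B (-4.61, SE 0.27, adjusted p = 0.00329), SPRR1A (-3.42, SE 0.25, adjusted p = 0.0102) and SPRR3 (-2.67, SE 0.29, adjusted p = 0.0310), small proline-rich proteins that are crosslinked into the envelope, fell with the suprabasal keratin KRT13 (-1.71). The list's mean was -1.16 at the low spike level and -0.98 at the high one. Probe set 214549_x_at of SPRR1A shares probes with related transcripts, and its other, dimmer probe set gave -5.35 (adjusted p = 0.0354 over all probe sets). The SPRR1A call was lost without C/EBPbeta-2 replicate 3 (adjusted p = 0.0713) or control replicate 3 (0.0843), and those of SPRR3 (0.0814 to 0.202) and KRT13 (0.0786 to 0.126) without any array but control replicate 2.

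Of 13 measured S100 and antimicrobial proteins, SLPI and PI3 fell, 2 members, and 0 rose. The list was lower as a set at the preset correlation (mean -1.52, median -0.28, camera adjusted p = 3.16e-07), and not called with an estimated one (adjusted p = 0.127). With p adjusted over the list alone, 4 fell, adding S100A7 (-2.35) and S100A8 (-3.61, SE 0.87, adjusted p = 0.334 over all genes), and 1 rose, RNASE7 (1.27). The list's mean was -1.46 at the low spike level and -1.54 at the high one. The PI3 call (log2 difference -4.65, SE 0.49, adjusted p = 0.0310) was lost without any of C/EBPbeta-2 replicates 1 to 3 (adjusted p 0.102 to 0.159) or control replicate 3 (0.202).

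Kallikreins and serine protease inhibitors moved in both directions. Of 14 measured genes, the clade B serpins SERPINB7 and SERPINB3 rose, the kallikrein KLK10 fell and 11 were not called. In tests adjusted over the list alone 3 rose, adding SERPINB4 (1.93), and 4 fell, adding KLK5 (-1.62), KLK7 (-2.22) and KLK8 (-1.11). The mean was 0.18, the median -0.18 and the camera direction down (adjusted p = 0.264), and the list was not called. SERPINB3 was read at 209719_x_at, which shares probes with related transcripts such as SERPINB4. Both serpin calls were lost whichever array was left out (SERPINB7 adjusted p 0.0617 to 0.202, SERPINB3 adjusted p 0.0713 to 0.219), and SERPINB3 also with each array centred on its median (0.0514, in a range of 0.0159 to 0.219 over the alternatives).

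Genes of epithelial junction and polarity fell as a set (mean -0.58, median -0.34, camera adjusted p = 1.32e-08), with adjusted p = 0.0353 with an estimated correlation. CDH1, the adhesion protein E-cadherin of epithelial cells, fell from 10.60 to 8.46 (log2 intensity; difference -2.14, SE 0.22, adjusted p = 0.0282), and the tight junction protein CLDN7 fell from 9.02 ± 0.40 to 6.74 ± 0.03 (SD, n = 3; difference -2.28, SE 0.22, adjusted p = 0.0273). These were 2 of 25 measured genes of epithelial junction and polarity, and 0 rose. With p-values adjusted over the list alone, 4 fell and 0 rose, adding the tight junction protein OCLN (-2.48, adjusted p = 0.0897 over all genes) and the connexin GJB2 (-2.44). The list's mean was -0.50 at the low spike level and -0.62 at the high one, and the calls were lost whichever array was left out (CLDN7 adjusted p 0.0523 to 0.136, CDH1 adjusted p 0.0617 to 0.167). That of CDH1 was lost also with the mean of its probe sets (0.194; 0.0109 to 0.251 over the alternatives).

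Epithelial transcription and splicing factors were lower as a set at the preset correlation (mean -0.81, median -0.50, camera adjusted p = 5.79e-06), but were not called with an estimated one (adjusted p = 0.179) or by fry (adjusted p = 0.159). Of 15 measured genes limma called 0 singly, with 4 at an unadjusted p under 0.05. For p adjusted over the list alone, 3 fell and 0 rose: the ETS factors EHF (-4.96, SE 0.90, adjusted p = 0.163 over all genes) and ELF3 (-0.999), and GRHL3 (-2.13), a grainyhead factor of the epidermal barrier. EHF was called in 2 of 17 alternatives (adjusted p 0.0170, without control replicate 2, to 0.621). The splicing regulator ESRP1 differed by -1.66 (-0.97 without C/EBPbeta-2 replicate 1). At the low spike level the list's mean was -0.86 and at the high one -0.79.

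Mesenchymal markers were not called as a set. Of 25 measured markers of mesenchymal transition, 1 fell, FAP (-3.21, SE 0.35, adjusted p = 0.0327), and 0 rose. In tests adjusted over the list alone 2 fell, FAP and FOXC2 (-1.65), and 2 rose, the matrix protein SPARC (2.53) and the ectoenzyme NT5E (1.24). POSTN differed by -2.54 (adjusted p = 0.885; -1.35 without control replicate 1). The mean was -0.10, the median 0.09 and the camera direction down (adjusted p = 0.593). The FAP call was lost whichever array was left out (adjusted p 0.0533 to 0.159).

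KRT14, a keratin of basal epithelial cells, fell from 13.34 ± 0.22 to 10.33 ± 0.67 (SD, n = 3; difference -3.00, adjusted p = 0.0347), 1 of 12 measured genes of basal keratins and the hemidesmosome, and 0 rose. KRT14 was 1 of 3 that fell, with 0 rising, when adjusted over the list alone, beside KRT15 (-2.28) and KRT16 (-1.76), and the list was not called (mean -0.33, adjusted p = 0.385). The KRT14 call was lost without any array but C/EBPbeta-2 replicate 2 (adjusted p 0.0905 to 0.219) and with each array centred on its median (0.0560; 0.0120 to 0.219 over the alternatives). Of 19 luminal and milk protein markers limma called 0, also when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.264), with MUC1 at -1.46, CD24 at -0.27 and KRT8 at -0.24. The lists of markers of other cell types were not called over all 6 arrays with all probe sets. Of 15 fibroblast and other stromal cell markers limma called 0, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.207), with DCN at -2.61, FBLN1 at -0.91 and COL1A2 at 0.39. The stromal list was called, as lower, with dim probe sets left out (mean -0.66, adjusted p = 0.0163, against a mean of -0.24 with all) and without control replicate 3 (mean -0.36, adjusted p = 0.0297). Of 11 leukocyte markers limma called 0, with 1 at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone, CD14 (0.92), beside MS4A1 at -0.50 and CSF1R at -0.47 (list adjusted p = 0.593).

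EGF family ligands and receptors were higher as a set at the preset correlation (mean 0.51, median 0.12, camera adjusted p = 0.000864), and not called with an estimated one (adjusted p = 0.127). EREG, the ligand epiregulin, rose from 5.56 ± 0.34 to 7.72 ± 0.18 (SD, n = 3; difference 2.16, SE 0.22, adjusted p = 0.0273), 1 of 15 measured EGF family ligands and receptors, and 0 fell. When p was adjusted over the list alone, 2 rose and 0 fell, adding the ligand NRG1 (2.06, adjusted p = 0.292 over all genes), and TGFA differed by 0.88. The list's mean was 0.50 at the low spike level and 0.52 at the high one. The EREG call was lost without any array but control replicate 2 (adjusted p 0.0894 to 0.138) and with the mean of its probe sets (log2 difference 1.12, adjusted p = 0.0594), and its adjusted p ranged from 0.00859 to 0.251 over the alternatives.

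Among genes of TGF-beta and BMP signalling, INHBA, the activin A subunit, rose (227140_at; log2 difference 4.77, SE 0.49, adjusted p = 0.0305), as did the inhibitory SMAD7 (1.22), 2 of 24 measured genes, and 0 fell. By p adjusted over the list alone 5 rose, adding the activin antagonist FST (2.62, adjusted p = 0.199 over all genes), the ligand TGFB2 (2.41) and the receptor TGFBR1 (0.65), and 2 fell, ID3 (-1.34) and LTBP1 (-1.48). FST was called in 3 of 17 alternatives (adjusted p 0.0397 to 0.732). The list's mean was 0.08, its median -0.11 and its camera direction down (adjusted p = 0.727). The INHBA call was lost without any array but C/EBPbeta-2 replicate 1 (adjusted p 0.0523 to 0.178) and that of SMAD7 whichever array was left out (0.0800 to 0.219). SMAD7 lost it also with the trended and robust prior (0.166), with dim probe sets left out (0.0880), with each array centred on its median (0.0590), with a spike term (0.0608) and over the genes without _x_at and _s_at probe sets (0.0518), in a range of 0.0215 to 0.479 over the alternatives.

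Of 29 measured collagens and matrix proteins, the basement membrane chain COL4A6 fell (-2.50, SE 0.20, adjusted p = 0.0132) and 0 rose. With the p adjusted over the list alone 2 fell, adding COL4A5 (-1.12), and 1 rose, CCN1 (2.47), and CCN2 differed by 2.36 (1.33 without control replicate 3). The COL4A6 call was lost without C/EBPbeta-2 replicate 2 (adjusted p = 0.0547), control replicate 1 (0.0775) or control replicate 3 (0.0920), and with the mean of its probe sets (log2 difference -1.38, adjusted p = 0.0572; 0.00593 to 0.191 over the alternatives). Of 24 matrix proteases and inhibitors limma called 0, with 6 at an unadjusted p under 0.05. Of these, SERPINE2 (-3.68, SE 0.60), TIMP3 (-1.65) and MMP28 (-1.41) fell and the cathepsin CTSB (1.15) rose, 3 and 1 when adjusted over the list alone. MMP28 was read at its brightest probe set, and a dimmer one fell by 3.83 (adjusted p = 0.00269 over all probe sets). SERPINE2 had an adjusted p of 0.115 over all genes and was called in 3 of 17 alternatives (adjusted p 0.0210, without control replicate 2, to 0.401). The protease PLAU differed by 1.72 (1.14 without control replicate 3). Neither list was called (adjusted p = 0.390 and 0.163).

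Proliferation genes were higher as a set at the preset correlation (mean 0.46, median 0.45, camera adjusted p = 2.73e-10), but were not called with an estimated one (adjusted p = 0.164) or by fry (adjusted p = 0.118). All 30 measured genes had a positive difference, 6 of them with all 3 C/EBPbeta-2 arrays above all 3 control arrays, and limma called 0, also when adjusted over the list alone, with 4 at an unadjusted p under 0.05. The mitotic kinase gene BUB1 differed by 0.77, the ribonucleotide reductase gene RRM2 by 0.74 and the cyclin gene CCNA2 by 0.69. Without C/EBPbeta-2 replicate 2, BUB1 differed by 0.31 and CCNA2 by 0.46, and the mean of the list was 0.33. The list's mean was 0.74 at the low spike level and 0.32 at the high one. Of 12 genes of G1 control and senescence limma called 0, with 1 at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone, CDKN1C, a cyclin-dependent kinase inhibitor (-3.80, SE 0.63, adjusted p = 0.125 over all genes). CDKN1C was called in 3 of 17 alternatives (adjusted p 0.0142 to 0.459). CCNE2 differed by 0.77 and CCND2 by 0.51, and the list had a mean of -0.13, a median of 0.16 and camera direction up (adjusted p = 0.752).

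**Figure D3:**
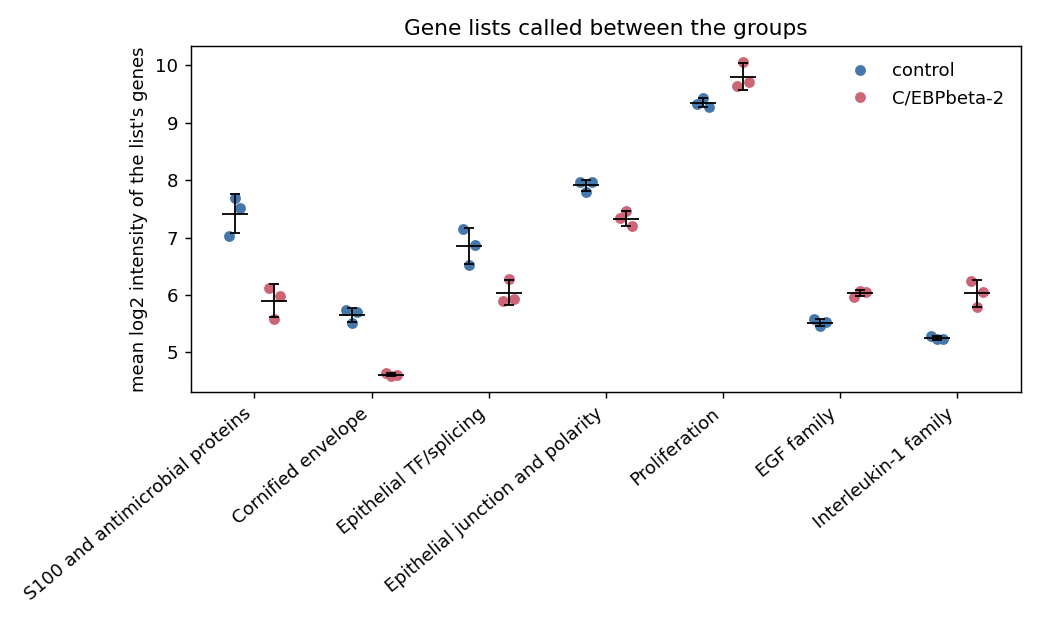
Mean log2 intensity of the measured genes of the 7 called lists on each array, 1 point per array, with colour for the group. The C/EBPbeta-2 arrays lie lower for the cornified envelope list (mean difference -1.04) and higher for the proliferation list (0.46).

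The remaining lists were not called. Of 19 genes of the oxidative stress and NRF2 response (list adjusted p = 0.207), 1 fell, also when adjusted over the list alone, the aldehyde dehydrogenase gene ALDH3A1 (-2.69, SE 0.34, adjusted p = 0.0496). Its call was lost whichever array was left out (adjusted p 0.0555 to 0.277), with each array centred on its median (0.0631), with a spike term (0.0656) and over the genes without _x_at and _s_at probe sets (0.0519; 0.00955 to 0.389 over the alternatives). AKR1C3 (-1.27) and AKR1C2 (-1.15) were not called. In the next 5 lists limma called 0 genes, also when adjusted over the list alone. Among 14 p53 targets, with 1 at an unadjusted p under 0.05, TP53I3 differed by -1.48, SESN2 by 0.47 and CDKN1A by 0.44, and the list's mean of -0.02 lay against a median of 0.08 and camera direction up (adjusted p = 0.936). Among 23 genes of glycolysis and the hypoxia response (3 at an unadjusted p under 0.05; list adjusted p = 0.163) NDRG1 differed by 1.13, CA12 by 0.95 and P4HA1 by 0.85. Among 14 genes of cholesterol biosynthesis (0 at an unadjusted p under 0.05; list adjusted p = 0.163) INSIG1 differed by -0.52, LSS by -0.38 and FDPS by -0.32. Among 19 genes of unfolded protein and amino acid stress (0 at an unadjusted p under 0.05; list adjusted p = 0.593) SLC7A11 differed by 0.56, DDIT4 by -0.51 and ATF5 by 0.45. Among 14 genes of autophagy and the lysosome (1 at an unadjusted p under 0.05; list adjusted p = 0.593) LAMP2 differed by -0.59, ATG5 by 0.54 and CTSD by -0.49.

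Of the 7 called lists, the cornified envelope and junction lists kept their call with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way, called 5 of the 7, the cornified envelope (adjusted p = 0.00236), EGF family (0.00774), junction (0.00774), S100 and antimicrobial (0.0111) and interleukin-1 lists (0.0196), and 0 of the other 21. The camera direction of lists that were not called is not settled. Over 18 alternatives it turned in 8 for p53 targets, 6 for interferon-stimulated genes, and 5 each for G1 control and senescence and for unfolded protein and amino acid stress. It turned in 3 each for cytokines and chemokines, mesenchymal markers and TGF-beta and BMP signalling. A call at the preset correlation alone does not settle an effect of the group. List genes that share an effect of the array can be called there without any effect of the group, as 62 of 100 simulated lists were. The shared effect in that simulation was not fitted to these lists, so this share does not carry over to the 7. Their estimated correlation was -0.038 (EGF family), -0.017 (junction) and -0.012 (cornified envelope), and 0.064 to 0.147 for the other called lists. Without control replicate 3, 14 lists were called, adding cytokines and chemokines (adjusted p = 0.0270), acute-phase and complement (0.0478), fibroblast and other stromal cell markers (0.0297), matrix proteases and inhibitors (0.0231), unfolded protein and amino acid stress (0.00106), cholesterol biosynthesis (0.0379) and glycolysis and hypoxia response (0.0474). Basal keratins and hemidesmosome were called without C/EBPbeta-2 replicate 3 (0.0340), and oxidative stress and NRF2 response without C/EBPbeta-2 replicate 1 (0.0179) and without _x_at and _s_at probe sets (0.00401). With dim probe sets left out, 9 lists were called, adding the stromal markers (0.0163) and the matrix proteases and inhibitors (0.0307).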

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

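Both control probe sets below were singled out after their values were seen. Of the 62 control probe sets outside the comparison, 2, both for the same human gene, had all 3 C/EBPbeta-2 arrays above all 3 control arrays, with log2 differences of 0.94 and 0.97. By chance 3.1 of 62 would lie higher on all 3 arrays, and 0 lay lower on all 3.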

How the results depend on the processing

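The term for the spike level, the ACTB covariate and the fit of 4 arrays were chosen after seeing the data. Leaving out 1 array gave 5 to 37 probe sets, all at least 2-fold, 7 to 57 genes and 6 to 14 lists, against 36, 52 and 7, with fewer arrays in each fit. The replicate numbers did not pair the arrays: same-numbered arrays had correlations of deviations from the group means of -0.45, -0.55 and 0.42, while C/EBPbeta-2 replicates 1 and 2 correlated best with control replicates 2 (0.637) and 1 (0.659), so whether the numbers mark shared cultures stays in doubt and the block joins unlike arrays. With the replicate block limma called 0 probe sets, 0 at least 2-fold and 0 genes (1701 probe sets at unadjusted p under 0.05), and 7 lists. Without dim probe sets 78 probe sets were called, and with the trended and robust prior 67, all at least 2-fold. Array weights gave 122 probe sets, all at least 2-fold, and 122 genes. The ACTB covariate gave 78 probe sets, all at least 2-fold, and 106 genes. The 4 arrays with a high spike level gave 6 probe sets, all at least 2-fold, and 13 genes. At an adjusted p under 0.01, 10 probe sets were called, and limma's treat against a 2-fold change also called 10. Without pooling of variances 0 were called (2055 at unadjusted p under 0.05). With an estimated correlation 2 lists were called. Apart from the smaller numbers of arrays or of tested probe sets, the cause was not tested. The 52 genes kept their sign under quantile normalization, centring and the other choices of probe set where tested, while leaving out an array could not turn it, as their groups did not overlap, and the median of all probe sets moved by less than 0.04 under each. Over named genes and alternatives, 1352 results stayed on their side of the threshold, 145 lost a call, 19 gained one and 7 reversed, none of them called. Over lists, 444 stayed, 9 lost a call, 12 gained one and 38 reversed, none of them called. Leaving out 1 array moved CD24 from -0.79 to 0.089 (positive without control replicate 1), KRT8 from -0.46 to 0.022 (positive without C/EBPbeta-2 replicate 2), SESN2 from -0.056 (without C/EBPbeta-2 replicate 3) to 0.79 and SLC7A11 from -0.071 (without control replicate 2) to 1.25. KRT8 was 0.0033 in the 4 arrays, and without _x_at and _s_at probe sets P4HA1 was -0.0092 and AKR1C2 0.033. No signal over background was used here, so folds of genes near the array medians are less certain.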

Other observations

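Further genes changed outside the rule for named genes, chosen here after their values were seen. Among those that rose were ENC1, an actin-binding protein (log2 difference 2.73, SE 0.30, adjusted p = 0.0334), GULP1, an engulfment adaptor (2.30), TPRG1 (2.15), RAB7B, a small GTPase of endosomal transport (2.13), TMEM158 (2.08), CEMIP2, a cell-surface hyaluronidase (1.71), and the tetraspanin TSPAN13 (1.51). Among those that fell were CSTA, the protease inhibitor cystatin A of the cornified envelope (-3.20, SE 0.40, adjusted p = 0.0496), PITPNM3 (-2.85), the myosin MYO5C (-2.83), KYNU, kynureninase (-2.80), and SFRP1, a secreted Wnt antagonist (-2.63). FXYD3 (-2.41), the grainyhead-like factor TFCP2L1 (-2.18) and RAB27B, a GTPase of secretory vesicles (-2.14), fell as well. Each value is a limma difference of 3 against 3 arrays in which the groups did not overlap, and each of these genes lost its call in at least 4 of the 6 fits that left out 1 array, where ENC1 reached an adjusted p of 0.212 and CSTA of 0.277. Processing choices also ended calls. Quantile normalization did so for ENC1 (adjusted p = 0.0753), CSTA (0.0646) and CEMIP2 (0.0661), and centring for CSTA (0.0590), MYO5C (0.0677), PITPNM3 (0.0588) and RAB7B (0.0590). The mean of a gene's probe sets ended those of SFRP1 (0.132), RAB27B (0.0677) and RAB7B (0.0756), and the trended and robust prior those of CEMIP2 (0.0735) and RAB7B (0.0536). The spike term ended that of RAB7B (0.0540), and leaving out _x_at and _s_at probe sets those of KYNU (0.0855), CSTA (0.0519), MYO5C (0.0518) and RAB7B (0.0518). Over all alternatives the adjusted p of these genes ranged from 0.00409 (RAB27B and TMEM158) to 0.328 (TFCP2L1).

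All tests in the rest of this part were chosen after the result was seen, except the reassignment of the ACTB values, the random lists matched to the proliferation list, and the count of lists over the splits of the arrays. The labelled split called 36 probe sets, 36 at least 2-fold and 52 genes, each the only 1 of 10 splits of the 6 arrays to do so, with 0 as the highest count of the other splits. It called 7 lists, and 2 of 10 splits did so: C/EBPbeta-2 replicates 1 and 2 with control replicate 3 against the rest also gave 7, the highest of the other splits. With 10 splits a share under 0.05 cannot be reached.

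CEBPB was not higher on the arrays labelled C/EBPbeta-2. An exchange of 1 array between the groups is argued against, since the 9 splits that exchange 1 array of each group called at most 0 probe sets by limma, against 36. That the probe set reads no part of the introduced transcript stays open: a probe set that reads only the cell's own CEBPB need not be higher, and the probe position was not used here. This explanation does not predict the size of the difference, -0.62. RNA integrity was tested only as the ACTB value marks it. The ACTB covariate left the difference at -0.62 (SE 0.30), and the ACTB value hardly differed between groups. That difference never passed the test, so RNA integrity also stays open. A lower level of the cell's own CEBPB in the presence of the isoform may also account for the difference and was not tested.

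Arrays varied more across the groups than between them, with C/EBPbeta-2 replicate 1 close to control replicate 2 (r = 0.976) and C/EBPbeta-2 replicate 2 close to control replicate 1 (r = 0.979). This may reflect RNA integrity as the ACTB value marks it. Of 100 assignments of the ACTB values to the arrays, 3 called at least 78 probe sets, the count of the real one. The 3 include the real one, and the median over the others was 11. Another assignment called 2123, far more than the real one, and the cause of that count was not tested. The GAPDH value did not mark the same arrays. It was 0.22 on C/EBPbeta-2 replicate 2 and 0.12 on control replicate 1, where the ACTB value was highest. A labelling batch marked by the poly-A spike level is likewise possible: as a term, the low-spike pair called 52 probe sets, the most of the 9 pairs of 1 array from each group (rank 1), which chance gives 1 time in 9. The next pair, C/EBPbeta-2 replicate 1 with control replicate 2, called 48, and since these pairs share their sides of the variation, the tests do not separate the 2 explanations from each other or from a difference between cultures.

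Proliferation genes were higher on the arrays labelled C/EBPbeta-2 by a mean of 0.46. A general rise of genes at this expression level is argued against, since that mean lay at percentile 99.99 of 10000 random lists matched on level, whose median was 0.05. Genes of the random lists were drawn singly, while those of the proliferation list were correlated (estimated correlation 0.147). The percentile may therefore overstate how rare such a mean is. Whether RNA integrity is the source of this mean could not be decided with the ACTB value. That value differed by 0.085 between groups, against SDs of 0.57 (C/EBPbeta-2) and 0.78 (control), so as a covariate it could move the mean little. With it as a covariate the mean was 0.45 (SE 0.15 over the arrays), from which nothing is concluded. RNA integrity stays open, also where this value does not mark it. In the pair of arrays with the highest ACTB values the mean was 0.74, against 0.32 in the other 4, so its size was not even across them. The mean was larger than in any other of the 10 splits (1 of 10, highest other 0.33), too few for a share under 0.05. A faster growth of the cells with C/EBPbeta-2 may be the cause, as a hypothesis, and neither this nor a difference in density at harvest was tested.

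A further hypothesis was that called genes lie next to each other and that neighbouring genes change together. Of 51 called genes with a known place, 11 had a called gene of the same direction within 10 protein-coding genes, against at most 10 in 10000 random draws (permutation p = 1e-04, the smallest these draws can give). The pairs were SPRR1A, SPRR3 and SPRR1B, IRX3 and IRX5, KRT13 and KRT14, SERPINB3 and SERPINB7, and PI3 and SLPI. Without pairs whose symbols share their first 3 letters the count was 2 (permutation p = 0.513), so clustered members of 1 gene family may account for it.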
